A study of Mus musculus with 8 samples.

How the data were processed

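The study measured total RNA by Illumina sequencing in 8 libraries of mouse E14 embryonic stem cells, 2 libraries in each of 4 groups: the GSK3α line and the GSK3β line, each untreated and with 5 µM 3MB-PP1 for 2 h after 6 h without serum. The labels state no vehicle for the untreated cells and give no line without a mutant kinase, so an action of the compound on other targets has no control here. Each paralog is represented by 1 line, and nothing in the labels says whether the replicates of a group were separate cultures, so the p-values measure the spread between these libraries only.

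The authors aligned the reads with TopHat2 and summarised them with Partek on the mouse genome build mm10, per the labels, which give no versions, no gene annotation, no strand setting and no filter. The deposited table holds signal values: gene counts that the authors estimated and scaled so that the third quartile over the listed genes was equal in all libraries to within 0.0548%. It is therefore not a table of raw counts, although it is named as counts. The smallest value of each library recurs many times and was taken as 1 read; in these units 63.0 to 67.2% of the values up to 20 reads were whole to within 0.1, and the rest were fractions, as when reads are shared between genes. Reads assigned to genes were estimated as the sum of a library divided by its smallest value, which gave 21.5 to 32.4 M reads. Of the 48321 genes listed, 17488 had values and 30833 had none in any library, and none had values in part of the libraries. Every gene with values had at least 1 estimated read in all 8 libraries, so a gene that was off in any library cannot be seen. The names of 27 genes had been turned into dates, 23 of them with values, and these were left as they stood.

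Genes with a mean value of at least 1 over the 8 libraries were tested, which kept 13959 and left out 3529. The values were used on the scale log2(value + 1), where the added 1 understates the fold change of genes at low values. The test was limma-trend (limma 3.58.1 in R 4.3.3, data.table version 1.17.8) with 1 mean for each of the 4 groups and 1 shared estimate of the spread from 4 residual degrees of freedom. Adjusted p-values are from limma with the Benjamini-Hochberg correction over all tested genes in each comparison, two-sided, with a threshold of 0.05, and SE is that of the limma fit. The comparisons were inhibitor against untreated in each line, the difference of these changes between the lines, the untreated lines against each other, and the average effect of the inhibitor with line as a term in the model, which makes 5 comparisons. The average was fitted with terms for line and inhibitor in place of the 4 group means, so its residual degrees of freedom differ. A response that differed between the lines counts toward its spread. The design had named a test for counts first and limma-trend for a table without counts, and the second was used. The median SE was 0.0634 for a comparison within a line or between the untreated lines, 0.0897 for the difference and 0.0510 for the average. Intervals are at 95%.

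The 30 gene lists, the comparisons, the rule for the genes named in the text and all alternatives except the thinning of reads were fixed before the data were examined. Lists were tested with camera from limma at a preset correlation between genes of 0.01, with the Benjamini-Hochberg correction over the 28 lists that had at least 5 tested members. The list of mitochondrially encoded genes had 0 tested members, since none of those genes has a value in the table, and that of replication-dependent histones had 4, so these were described only. As alternatives the correlation was estimated for each list, and the lists were tested with fry. That test asks whether the genes of a list move on balance in 1 direction. Unlike camera, it does not set them against the other genes, so a pass with fry and a pass with camera answer different questions. The calls of cholesterol and fatty acid synthesis, ERK feedback and Nodal targets in the GSK3α line held with an estimated correlation, and no list call of the other comparisons did. In the lists whose camera result passed, the direction of the test, the mean and the median of the log2 changes had the same sign.

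The rule named 192 genes, among them Gsk3a, Gsk3b and a fixed set of pathway genes. It took the 10 largest rises and falls past the threshold of each comparison but the average over both lines. Their libraries did not overlap between the groups and their mean was at least 5 in the higher group. For the difference between the lines, the changes of the treated libraries from the untreated mean did not overlap between the lines. There the highest of the 4 group means was at least 5. The rule also took up to 4 members of each list past the threshold or otherwise 2. Last came 10 genes in each direction past the threshold in both lines. The minimum of 5 had been set for CPM and was applied to the deposited values. Some genes under the rule are not reported here. Genes named outside the rule are marked as chosen after their values were seen. Positions are from GENCODE M21 on GRCm38, the assembly of mm10, matched by symbol for 13515 of the 13959 tested genes (96.8%).

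Recovery was tested on simulated data. In a simulated comparison within a line over 13944 genes, 60% of 50 genes changed 1.25-fold were recovered, 98% of 50 changed 1.5-fold, 100% of 50 changed 2-fold and 98% of 50 changed 0.5-fold, and 9 of the 187 calls were genes left unchanged. The changed genes were drawn from those with a mean of at least 5, and 1 dispersion was set for every gene. These shares therefore do not cover changed genes at lower values or genes with a wider spread between replicates. Nor do they cover changes under 1.25-fold. The median absolute log2 change of the genes called below was smaller than that, at 0.22 in the GSK3α line and 0.23 in the GSK3β line. Alternatives were median-of-ratios (RLE) scaling, limma-voom on the estimated reads, no filter, a stricter filter of at least 1 in at least 4 libraries, a pseudocount of 0.1 or, for the correlation of the lines, 2, each line fitted alone, replicate number as a block, a fold threshold of 1.5, each library left out in turn, and the estimated reads thinned to the smallest library in 5 draws. The plots and the summaries behind them were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.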

Results

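RNA was sequenced from mouse embryonic stem cells of the E14 line in 8 libraries, 2 in each of 4 groups. The cells came from 2 transgenic lines. In the GSK3α line the gene of the kinase GSK3α was knocked out and the kinase was expressed from a transgene with the L195G change. In the GSK3β line the gene of its paralog GSK3β was knocked out and that kinase was expressed from a transgene with the L132G change. Both kinases act in many pathways, among them Wnt signalling, where they mark β-catenin for destruction. The changes are of the analog-sensitive kind, which opens the ATP pocket of a kinase to bulky inhibitors such as 3MB-PP1. Cells were kept without serum for 6 h and were then left untreated or given 5 µM 3MB-PP1 for 2 h, so each line has its own untreated group. The recorded times are 6 h without serum for all groups and 2 h of treatment, with no time of harvest. A difference in the total time without serum could therefore not be told apart from the inhibitor.

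The reads assigned to genes were estimated at 21.5 and 22.7 M for the untreated GSK3α line and 26.0 and 26.4 M for the same line with inhibitor. The GSK3β line had 23.8 and 28.9 M untreated and 31.2 and 32.4 M with inhibitor. The libraries of every group correlated across genes with r = 0.998 on the log2 scale, a correlation across genes that are not independent replicates. The SD of the log2 difference between the libraries of a group ran from 0.118 to 0.143. The first principal component held 71.6% of the variance and separated the lines. The second held 11.2% and separated the treated from the untreated libraries of the GSK3β line, which lay at 13 and 7.39 untreated and at -11.3 and -8.36 with inhibitor. Libraries of the GSK3α line lay in the same order on it, at 0.951 and 0.212 untreated and at -0.986 and -0.906 with inhibitor.

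Each line carried more RNA of the paralog that its transgene encodes. Gsk3a (chromosome 7, 25228258 to 25237851, mm10) had a mean value of 158 ± 3.31 (SD, n = 2) in the untreated GSK3α line and 77.0 ± 1.21 in the untreated GSK3β line, a log2 difference of -1.02 between the GSK3β and the GSK3α line (adjusted p = 7.13e-14). Gsk3b (chromosome 16, 38089001 to 38246084) had 56.5 ± 2.50 in the untreated GSK3α line and 245 ± 14.9 in the untreated GSK3β line, a log2 difference of 2.10 (adjusted p = 2.91e-17). With inhibitor, Gsk3a in the GSK3α line fell by 0.16 on the log2 scale to 141 ± 0.253 (adjusted p = 0.0345). That call ended without any single library of the GSK3α line (log2 -0.14 to -0.18, adjusted p 0.0791 to 0.353) and without either inhibitor library of the GSK3β line (0.0512). Gsk3b did not pass the test in either line, with log2 values of -0.06 and 0.05. Reads of a transgene with the gene's coding sequence count toward the gene, so these values do not show whether the endogenous gene was silent.

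**Figure D1:**
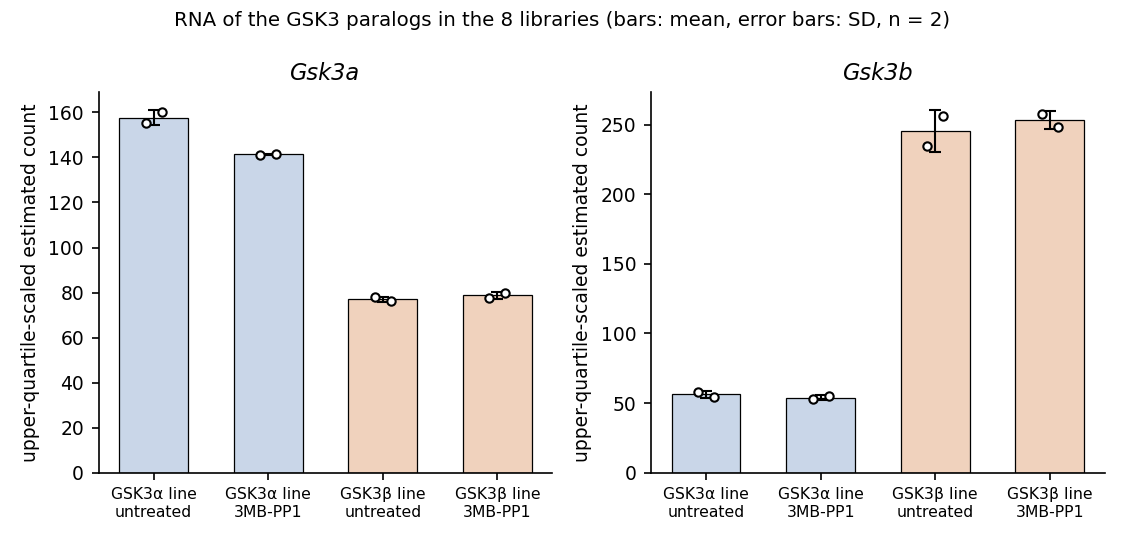
RNA of the GSK3 paralogs: upper-quartile-scaled estimated counts of Gsk3a (left) and Gsk3b (right) in the 4 groups. Points are the libraries, bars the means and error bars the SD (n = 2). The mean of Gsk3a is highest in the untreated GSK3α line (158). Gsk3b means are 245 and 253 in the GSK3β line and 56.5 and 54.0 in the GSK3α line.

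The comparison of inhibitor with no treatment in the GSK3α line asks which genes respond within 2 h when GSK3α is inhibited. Targets of Nodal signalling and feedback inhibitors of the ERK pathway fell. Lefty1, a secreted Nodal antagonist induced by Nodal itself (chromosome 1, 180935022 to 180938400), fell from 21.3 ± 0.523 (SD, n = 2) to 9.15 ± 0.417, a log2 change of -1.14 ± 0.07 (SE, adjusted p = 1.48e-08). Its neighbour Lefty2 fell from 47.1 ± 3.18 to 23.4 ± 0.686, a log2 change of -0.98 ± 0.05 (adjusted p = 4.93e-10). Enzymes of cholesterol synthesis rose by small amounts. Cyp51, the lanosterol demethylase, went from 75 ± 3.13 to 93.0 ± 0.0673 (log2 0.31 ± 0.04, adjusted p = 0.000491). Axin2, a feedback inhibitor and classical target of β-catenin, had 13.8 ± 0.160 untreated and 14.2 ± 0.430 with inhibitor, a log2 change of 0.04 ± 0.07 that did not pass the test (adjusted p = 0.869), with a 95% interval from -0.10 to 0.18.

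In the GSK3α line 4 of the 14 tested Nodal targets fell, 10 did not pass and none rose (1 higher and 9 lower adjusted over the list alone; list test adjusted p = 1.48e-12, and adjusted p = 0.0395 with an estimated correlation). Besides Lefty1 and Lefty2 these were Smad7, an inhibitory SMAD (log2 -0.62, adjusted p = 4.69e-07), and Skil, a repressor of SMAD activity (-0.26). Among the ERK feedback genes 5 of 14 fell and 9 did not pass (8 lower adjusted over the list alone; list test adjusted p = 8.02e-14, and adjusted p = 0.0378 with an estimated correlation). They included the ephrin receptor Epha2 (log2 -0.53), the ERK inhibitor Spry4 (-0.55) and the ERK phosphatases Dusp4 (-0.36) and Dusp6 (-0.25). Of the genes of cholesterol and fatty acid synthesis 9 of 31 rose and 22 did not pass (17 higher adjusted over the list alone; list test adjusted p = 2.43e-17, and adjusted p = 0.0151 with an estimated correlation). Msmo1 (log2 0.29), Insig1 (0.25) and Lss (0.21) were among them.

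A further 7 lists passed the preset test in the GSK3α line and did not pass with an estimated correlation. Targets of ATF4, the transcription factor of the amino acid and stress response, had 3 of 24 higher and none lower (7 higher adjusted over the list alone; adjusted p = 5.44e-08, and adjusted p = 0.195 with an estimated correlation). These were Chac1, a glutathione-degrading enzyme (log2 0.65, adjusted p = 0.000927), the pseudokinase Trib3 (0.35) and Atf4 itself (0.18). Formative and primed pluripotency genes had 4 of 17 lower (7 adjusted over the list alone; adjusted p = 1.62e-05, and adjusted p = 0.0892 with an estimated correlation), among them the transcription factors Otx2 (log2 -0.29) and Foxd3 (-0.30) and the growth factor Fgf15 (-0.53). Targets of p53 had 1 of 19 lower, Pmaip1 at -0.34 (1 higher and 7 lower adjusted over the list alone; adjusted p = 5.64e-05, and adjusted p = 0.0626 with an estimated correlation). BMP targets had 1 of 9 lower, Id3 at -0.20 (2 adjusted over the list alone; adjusted p = 0.00577, and adjusted p = 0.138 with an estimated correlation). Naive pluripotency genes had 1 of 25 higher, Fgf4 at 0.14, and 1 lower, Nr5a2 at -0.18 (1 higher and 7 lower adjusted over the list alone; adjusted p = 0.00823, and adjusted p = 0.397 with an estimated correlation). Glycolysis and hypoxia genes had 1 of 27 lower, Slc2a1 at -0.14 (3 adjusted over the list alone; adjusted p = 0.0188, and adjusted p = 0.412 with an estimated correlation). Nucleolar MYC targets had 0 of 24 past the threshold, also adjusted over the list alone (adjusted p = 0.0269, and adjusted p = 0.434 with an estimated correlation). The list call of naive pluripotency genes ended without untreated replicate 2 of the GSK3α line (adjusted p = 0.0978). Those of glycolysis and of nucleolar MYC targets ended without that library (0.340 and 0.309) and without inhibitor replicate 2 of the line (0.265 and 0.226).

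The other 18 lists tested in the GSK3α line did not pass, with adjusted p from 0.0790 to 0.933. Of these, the Notch and heat shock lists passed without untreated replicate 1 of this line (0.0431 and 0.0251), and the 2-cell-like list passed without inhibitor replicate 1 (0.0161). Of the Wnt/β-catenin targets 1 of 16 fell, the growth regulator Myc (log2 -0.48, adjusted p = 0.00154), and 1 fell adjusted over the list alone. That list gave adjusted p = 0.223. Sp5 (log2 0.29), Lef1 (-0.14) and the mesoderm gene T (-0.24) did not pass. Of the Wnt pathway components 1 of 25 fell, Gsk3a (1 higher and 2 lower adjusted over the list alone). SRF and YAP targets had 1 of 19 lower, Ajuba at -0.16 (1 adjusted over the list alone), and G1/S genes had E2f1 higher (0.26) and Ccnd2 lower (-0.25) of 22 (1 higher and 3 lower adjusted over the list alone). No member passed, adjusted over all genes, among the 18 immediate early, 19 NRF2, 16 unfolded protein, 14 heat shock, 27 lysosome, 24 G2/M, 9 Notch and 8 Hedgehog genes. The same held for markers of other cell types, 8 of mesendoderm, 10 neural, 8 of fibroblasts, 10 of primitive endoderm, 9 of trophoblast and 14 of the 2-cell-like state, and for the 4 replication-dependent histone genes. Adjusted over the list alone, 1 neural, 1 Notch and 2 Hedgehog genes were higher, and immediate early genes had 1 higher and 1 lower. The regulators of naive pluripotency Nanog (log2 0.03), Esrrb (-0.03), Klf2 (0.03) and Tfcp2l1 (0.01) did not pass, nor did the immediate early genes Egr1 (0.41) and Fos (0.26). Some genes that often collect reads of ribosomal RNA, chosen after their values were seen, fell beside these groups, with log2 changes of -0.34 for Gm42418, -0.34 for Lars2 and -0.28 for Gm26917.

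In all, 123 of 13959 tested genes passed in the GSK3α line, 37 higher and 86 lower, of which 6 changed at least 1.5-fold. Further examples were the bZIP repressor Nfil3 (log2 0.55), the transporter Slc1a4 (0.36), Lrtm2 (0.56), Rab3a (0.50), Zfp61 (0.46), Ackr3 (0.44), Ccdc166 (0.37) and Jakmip1 (0.37), which were higher, and Trim36 (-0.55) and Fjx1 (-0.47), which were lower. The call of Ackr3 ended with limma-voom, without a filter and with replicate number as a block. The count was 55 without untreated replicate 1 of this line, 60 without untreated replicate 2, 16 without inhibitor replicate 1 and 25 without inhibitor replicate 2. Without a library of the GSK3β line, which shares the estimate of the spread, it was 186 without either untreated library and 92 or 96 without an inhibitor library. Of the 44 named genes that passed in this line, 9 passed whichever library was left out, among them Lefty1, Lefty2, Smad7, Spry4, Epha2, Sirt1, Cyp51 and Chac1. Among the other 35, the calls lost numbered 22 and 20 without untreated replicates 1 and 2 (adjusted p up to 0.256 and 0.222), 33 and 28 without inhibitor replicates 1 and 2 (up to 0.547 and 0.324), and 7 without either inhibitor library of the GSK3β line (up to 0.0711).

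The same comparison in the GSK3β line asks which genes respond when GSK3β is inhibited. Axin2 (chromosome 11, 108920349 to 108950783) rose from 14.5 ± 0.779 (SD, n = 2) to 39.8 ± 2.03, a log2 change of 1.39 ± 0.07 (SE, adjusted p = 5.66e-11). Lefty1 fell from 53.3 ± 2.18 to 8.34 ± 0.731 (log2 -2.54 ± 0.07, adjusted p = 2.04e-14), and Lefty2 from 97.7 ± 0.803 to 53.5 ± 0.693 (log2 -0.86 ± 0.05). Tfcp2l1, a regulator of naive pluripotency, went from 213 ± 14.3 to 350 ± 22.4 (log2 0.72 ± 0.04, adjusted p = 1.78e-09). Pou3f1, a transcription factor of the primed epiblast, went from 15.4 ± 2.03 to 5.81 ± 0.483 (log2 -1.26 ± 0.10, adjusted p = 6.04e-08). The serum- and glucocorticoid-induced kinase Sgk1 rose from 110 ± 5.57 to 202 ± 4.96 (log2 0.87 ± 0.04) and the cell cycle inhibitor Cdkn1a from 39.0 ± 3.66 to 74.4 ± 3.03 (log2 0.92 ± 0.05).

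Of the Wnt/β-catenin targets in the GSK3β line 3 of 16 rose, 3 fell and 10 did not pass, with equal counts adjusted over the list alone. The list itself did not pass with camera (adjusted p = 0.0626, and adjusted p = 0.216 with an estimated correlation), whereas it passed upward with fry (adjusted p = 0.00260). Axin2, Sp5 (log2 1.43, from a mean of 0.206 to 2.25) and the receptor Tnfrsf19 (0.97) rose, whereas Myc (-0.86), Lef1 (-0.63) and Ccnd1 (-0.12, chosen after its values were seen) fell. T had a log2 change of 0.14 and Cdx1 of 0.27, and neither passed. None of the 25 Wnt pathway components passed, also adjusted over the list alone. Naive pluripotency genes had 10 of 25 higher and 5 lower (12 and 5 adjusted over the list alone; adjusted p = 0.00269, and adjusted p = 0.218 with an estimated correlation). Klf4 (log2 0.59), Klf2 (0.53), Nr5a2 (0.38) and Esrrb (0.22) were higher, and the growth factor Fgf4 (-0.52) was lower. Nanog rose by 0.14, a call that ended without inhibitor replicate 1 of this line (0.11, adjusted p = 0.0900). Formative and primed genes had 12 of 17 lower and none higher (13 lower adjusted over the list alone; adjusted p = 2.15e-14, and adjusted p = 0.0590 with an estimated correlation). Among them were Fgf15 (log2 -1.18), Otx2 (-0.54) and the DNA methyltransferase Dnmt3a (-0.42). Mesendoderm genes had 2 of 8 higher, Gsc (0.54) and Evx1 (0.52), both at means under 2 (also 2 adjusted over the list alone; list adjusted p = 0.0918). Neural genes had 4 of 10 higher and 1 lower (4 and 2 adjusted over the list alone; list adjusted p = 0.195). The intermediate filament gene Nes (log2 0.51) and the tubulin Tubb3 (0.52) were higher and Neurod1 was lower (-0.46), while Sox1 (-0.28) and Pax6 (0.00) did not pass.

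Nodal targets in the GSK3β line had 9 of 14 lower and none higher (1 higher and 10 lower adjusted over the list alone; adjusted p = 1.38e-12, and adjusted p = 0.0590 with an estimated correlation). Smad7 was at -0.79 and Skil at -0.50. ERK feedback genes had 6 of 14 lower and 2 higher (7 and 3 adjusted over the list alone; adjusted p = 0.00367, and adjusted p = 0.172 with an estimated correlation). Dusp6 (log2 -1.17), Spry4 (-0.93) and Epha2 (-0.82) fell and the ephrin receptor Epha4 (0.64) rose. ATF4 targets had 17 of 24 higher and 1 lower (18 and 1 adjusted over the list alone; adjusted p = 2.15e-14, and adjusted p = 0.0916 with an estimated correlation). Examples were Chac1 (log2 1.0), Ddit3 (0.78), asparagine synthetase Asns (0.40) and the serine synthesis enzyme Psat1 (0.31). BMP targets had 3 of 9 higher and 2 lower (3 and 3 adjusted over the list alone; list adjusted p = 0.195). The HLH inhibitors Id3 (log2 0.66) and Id4 (0.71) were higher and Id2 was lower (-0.49). Cholesterol and fatty acid genes had 5 of 31 higher and 2 lower (9 and 5 adjusted over the list alone; list adjusted p = 0.246). Cyp51 had -0.05 and did not pass.

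Cell cycle genes in the GSK3β line were lower by small amounts. Of the G2/M genes 17 of 24 fell (20 adjusted over the list alone; adjusted p = 2.22e-11, and adjusted p = 0.0916 with an estimated correlation). They included the mitotic kinase Aurka (log2 -0.22), its activator Tpx2 (-0.17) and the cyclin Ccnb1 (-0.15). Of the G1/S genes 8 of 22 fell (10 adjusted over the list alone; adjusted p = 0.00137, and adjusted p = 0.0916 with an estimated correlation). The cyclins Ccne2 (-0.38) and Ccne1 (-0.22) were among these. Targets of p53 had 7 of 19 lower and 1 higher (9 and 2 adjusted over the list alone; adjusted p = 0.00183, and adjusted p = 0.0916 with an estimated correlation). The pro-apoptotic gene Bbc3 was lower (-0.49) and Cdkn1a was the member that rose. Immediate early genes had 7 of 18 lower and 2 higher (8 and 2 adjusted over the list alone; adjusted p = 0.00156, and adjusted p = 0.191 with an estimated correlation). Btg2 (-0.39) and Mcl1 (-0.31) were lower and Klf10 (0.35) higher, while Egr1 (0.22) and Fos (-0.09) did not pass. Heat shock genes had 7 of 14 lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.0194, and adjusted p = 0.369 with an estimated correlation). The chaperones Hspa1a (-0.68) and Hspa1b (-0.44) were lower. Those neighbouring genes are close copies, as are Lefty1 and Lefty2, and these values do not resolve reads shared between such copies. NRF2 targets had 7 of 19 lower, the same number adjusted over the list alone (adjusted p = 0.0429, and adjusted p = 0.369 with an estimated correlation). The antioxidant enzymes Hmox1 (-0.30) and Nqo1 (-0.26) were examples. Without untreated replicate 1 of this line the heat shock call ended (adjusted p = 0.0642). The NRF2 call ended without that library (0.0586), without inhibitor replicate 2 of this line (0.0893) and without either inhibitor library of the GSK3α line (0.0532 and 0.0533).

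Markers of primitive endoderm had 5 of 10 higher in the GSK3β line, and as many adjusted over the list alone (adjusted p = 4.37e-06, and adjusted p = 0.124 with an estimated correlation). The members that rose encode proteins of the extracellular matrix, among them the basement membrane collagens Col4a2 (log2 0.73) and Col4a1 (0.61) and the laminins Lama1 (0.56) and Lamb1 (0.39). The receptor gene Pdgfra, at a mean under 2, had -0.01 and did not pass. Nucleolar MYC targets had 8 of 24 higher and 2 lower (10 and 2 adjusted over the list alone; adjusted p = 0.00204, and adjusted p = 0.276 with an estimated correlation). Nop56 was at 0.13 and Rrp9 at 0.15. Lysosome and autophagy genes had 9 of 27 higher and 2 lower (11 and 3 adjusted over the list alone; adjusted p = 0.00314, and adjusted p = 0.151 with an estimated correlation). The protease Ctsl (0.29) and the transcription factor Tfe3 (0.18) rose. Glycolysis and hypoxia genes went both ways, with 5 of 27 higher and 7 lower (7 and 8 adjusted over the list alone; list adjusted p = 0.714). The glucose transporter Slc2a3 rose (0.29) and the mitophagy gene Bnip3 fell (-0.62). SRF and YAP targets had 1 of 19 higher and 2 lower, unfolded protein genes 2 of 16 higher and 1 lower, Notch targets 1 of 9 each way, Hedgehog targets 3 of 8 higher and 1 lower, and fibroblast markers 1 of 8 each way. Adjusted over the list alone these counts were 1 and 2, 3 and 2, 2 and 2, 3 and 1, and 1 and 1. Trophoblast markers had 2 of 9 higher, Tfap2c (0.85) and Tead4 (0.37), with 3 higher and 1 lower adjusted over the list alone. The 2-cell-like markers had 4 of 14 lower, such as Zscan4f (-0.28) of a family of close copies, and 4 adjusted over the list alone. None of these last 7 lists passed, with adjusted p from 0.0830 to 0.885. The trophoblast list passed without untreated replicate 2 (0.0236) or inhibitor replicate 2 (0.0423) of this line and the 2-cell-like list without the same libraries (0.0114 and 0.0423). None of the 4 histone genes passed. Nuclear copies of mitochondrial genes, chosen after their values were seen, rose beside these groups, with summed values of 10367 and 10026 untreated and 13808 and 13663 with inhibitor.

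In all, 2084 of 13959 tested genes passed in the GSK3β line, 1046 higher and 1038 lower, with a median absolute log2 change of 0.23, and 143 changed at least 1.5-fold. The neurofilament gene Nefm (log2 1.21), Spic (1.05), Pla2g7 (0.94), Mobp (0.90) and Lrrc15 (0.89) were among the higher genes, and the activin subunit Inhbb (-1.01), Tcf15 (-0.95), the cyclin Ccng2 (-0.91) and the lactate transporter Slc16a3 (-0.86) among the lower. The count was 1181 without untreated replicate 1 of this line, 2277 without untreated replicate 2, 864 without inhibitor replicate 1 and 1451 without inhibitor replicate 2. Of the 143 named genes that passed, 101 passed whichever library was left out. The calls lost numbered 29 and 8 without untreated replicates 1 and 2 (adjusted p up to 0.389 and 0.0959), 36 and 18 without inhibitor replicates 1 and 2 (up to 0.354 and 0.162), and 3 without either inhibitor library of the GSK3α line.

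**Figure D2:**
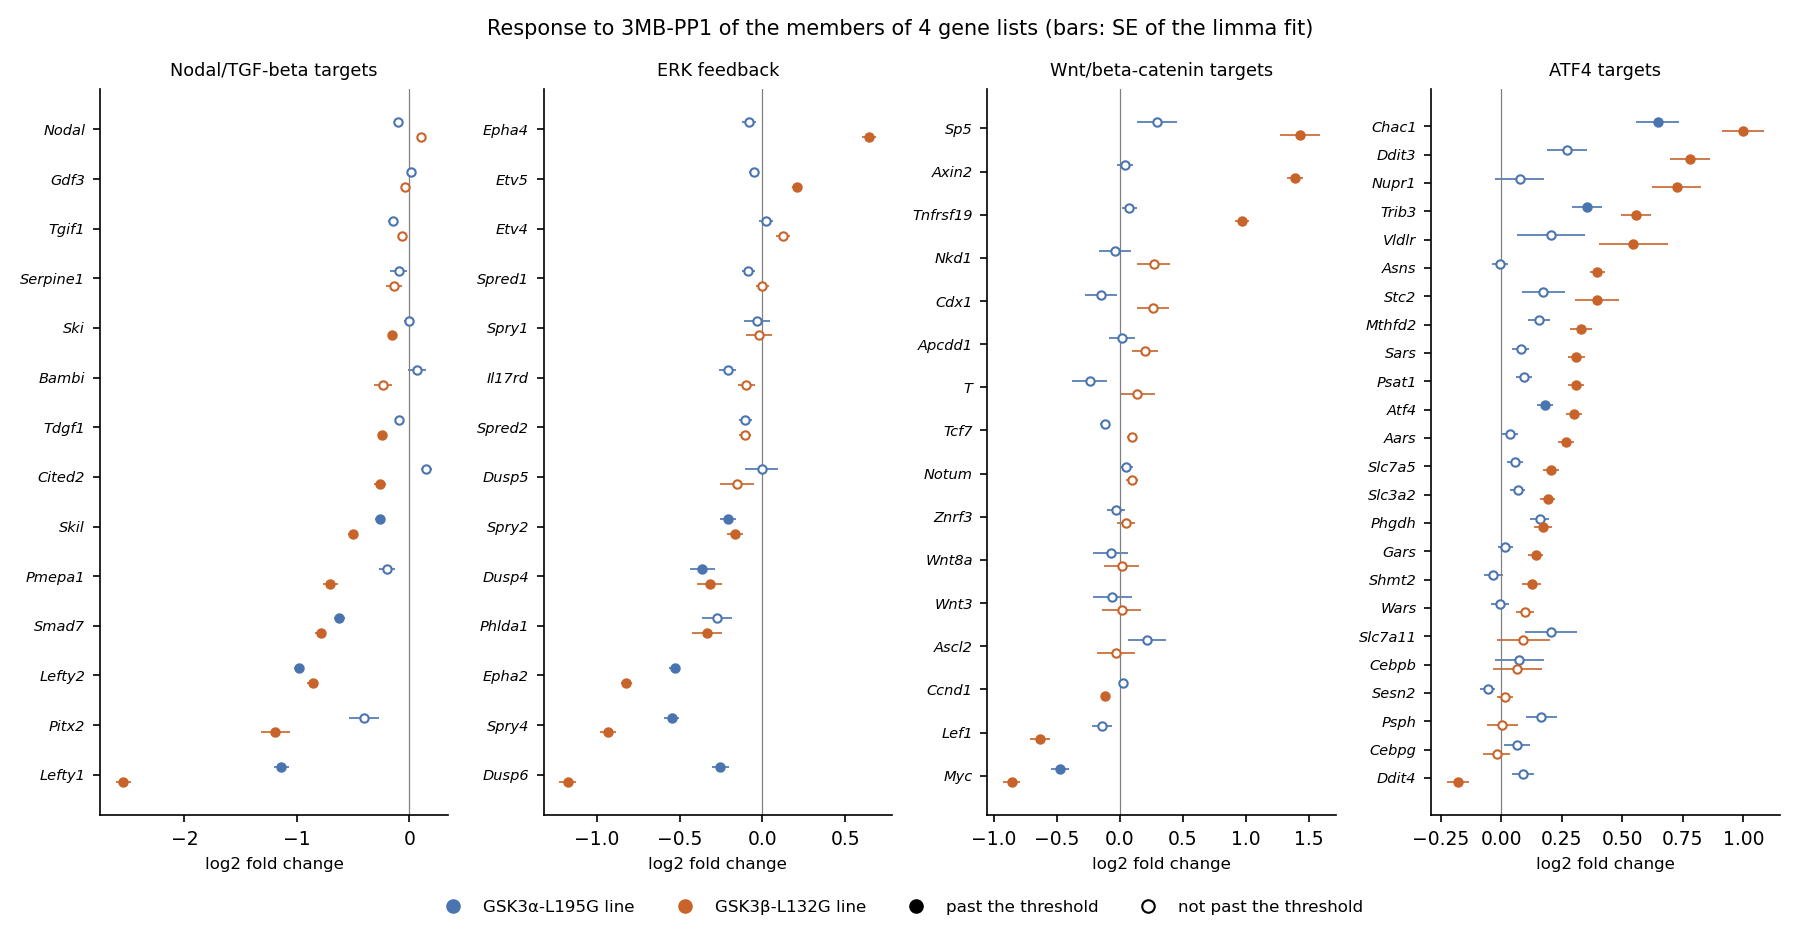
Members of 4 gene lists: log2 fold change with 3MB-PP1 in the GSK3α line (blue) and the GSK3β line (orange), with the SE of the limma fit as bars and filled points for genes past the threshold. Lefty1 fell in both lines (-1.14 and -2.54), and Axin2 rose in the GSK3β line (1.39) and had 0.04 in the other.

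Whether a response differed between the lines was tested directly, as the change in the GSK3β line minus that in the GSK3α line. Axin2 (difference 1.35 ± 0.09 log2, SE, adjusted p = 5.20e-08), Tfcp2l1 (0.71 ± 0.06, adjusted p = 7.03e-07) and Klf4 (0.53 ± 0.05, adjusted p = 6.16e-07) responded more positively in the GSK3β line. Lefty1 (-1.40 ± 0.10, adjusted p = 6.25e-08), Pou3f1 (-1.25 ± 0.14, adjusted p = 1.92e-05) and Dusp6 (-0.92 ± 0.07, adjusted p = 2.12e-07) responded more negatively. So did Cyp51 (-0.36 ± 0.06, adjusted p = 0.000516), which rose in the GSK3α line and had -0.05 in the other. Lefty1 had a higher level in the untreated GSK3β line than in the untreated GSK3α line, so its falls started from unlike levels. For Lefty2 (0.12, 95% interval -0.02 to 0.26), Smad7 (-0.16, -0.31 to -0.02) and Dusp4 (0.04, -0.18 to 0.27) the difference did not pass, which does not show that they responded alike.

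Of the genes tested, 911 differed in response, 506 more positive in the GSK3β line and 405 more negative, with 136 differing at least 1.5-fold. Naive pluripotency genes were more positive in the GSK3β line (9 of 25, with 1 more negative; adjusted p = 9.01e-06, and adjusted p = 0.148 with an estimated correlation). Formative genes (9 of 17 more negative; adjusted p = 9.88e-08), Nodal targets (5 of 14, with 1 more positive; adjusted p = 0.000278), G2/M genes (5 of 24; adjusted p = 3.74e-07) and cholesterol and fatty acid genes (9 of 31; adjusted p = 0.000917) were more negative, each with adjusted p = 0.148 with an estimated correlation. ATF4 targets (6 of 24 more positive, 1 more negative; adjusted p = 1.20e-06, and adjusted p = 0.165 with an estimated correlation) were more positive. Primitive endoderm markers (5 of 10; adjusted p = 4.53e-05), BMP targets (2 of 9, with 1 more negative; adjusted p = 0.00972) and Wnt/β-catenin targets (4 of 16, with 2 more negative; adjusted p = 0.0124) were too, again each with adjusted p = 0.148 with an estimated correlation. Adjusted over the list alone, the more positive and more negative members of these 9 lists numbered 12 and 3, 0 and 10, 1 and 9, 0 and 10, 2 and 10, 13 and 1, 5 and 0, 3 and 1, and 4 and 3 in the order given. The Wnt/β-catenin call ended without untreated replicate 1 of the GSK3α line (adjusted p = 0.0531). The remaining lists that passed were mesendoderm genes (adjusted p = 0.0314), nucleolar MYC targets (5.52e-05) and lysosome genes (0.0334) upward, and immediate early (0.00221), G1/S (0.0264) and NRF2 genes (0.0495) downward, with adjusted p from 0.154 to 0.433 with an estimated correlation. In that order 1 of 8, 2 of 24 and 5 of 27 members were more positive, immediate early genes had 1 of 18 more positive and 4 more negative, and 3 of 22 and 2 of 19 were more negative. In the adjustment over the list alone these numbered 1, 8 (with 2 more negative), 7 (with 1), 1 and 6, 4, and 6 (with 1 more positive). Of these calls G1/S ended without untreated replicate 1 of the GSK3α line (0.0553), mesendoderm without that library (0.0553) or untreated replicate 1 of the GSK3β line (0.0857), and lysosome without untreated replicate 2 (0.0546) or inhibitor replicate 2 (0.0509) of the GSK3α line. The NRF2 call ended without untreated replicate 1 (0.324) or inhibitor replicate 1 (0.113) of the GSK3α line, and without untreated replicate 1 (0.0725) or inhibitor replicate 2 (0.112) of the GSK3β line. Trophoblast markers passed without untreated replicate 2 of the GSK3α line (0.0469) or untreated replicate 2 (0.0263) or inhibitor replicate 2 (0.0446) of the GSK3β line, and heat shock genes without untreated replicate 2 of either line (0.0340 and 0.0342). ERK feedback genes did not differ as a list (adjusted p = 0.915), with 2 of 14 members more positive and 3 more negative, as many adjusted over the list alone. The count of differing genes was 450 and 472 without inhibitor replicates 1 and 2 of the GSK3α line, 566 without untreated replicate 1, 1339 without untreated replicate 2 and 353 without inhibitor replicate 1 of the GSK3β line. Of the 89 named genes that differed, 53 passed whichever library was left out, among them the 7 named with their p at the start of this comparison.

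The SD of the log2 changes was 0.111 in the GSK3α line, where the spread between replicates alone gives 0.0961, and 0.171 in the GSK3β line, where it gives 0.0912, which limits any correlation between them. The log2 changes had r = 0.08 (Spearman's rho 0.0733) over the 13959 tested genes and r = 0.192 (rho 0.174) over the 2140 genes past the threshold in at least 1 line. Over the 67 genes past it in both, a set chosen by its calls, r was 0.633 (rho 0.629). Here genes are not independent replicates and the lines share no untreated library. Of the 67 genes that passed in both lines, 48 fell in both (6.40 expected if the calls were independent) and 10 rose in both (2.77 expected). The other 9 went in opposite directions, no more than independent calls would give. These 4 counts were 28, 23, 1 and 4 without untreated replicate 1 of the GSK3α line, 32, 21, 8 and 3 without untreated replicate 2, 13, 10, 2 and 1 without inhibitor replicate 1 and 17, 13, 3 and 1 without inhibitor replicate 2. For the same libraries of the GSK3β line they were 82, 55, 13 and 14, then 98, 57, 15 and 26, then 42, 32, 5 and 5, and last 41, 30, 6 and 5. Genes that fell in both included Lefty1, Lefty2, Smad7, Skil, Epha2, Spry4, Dusp4, Dusp6, Myc, Fgf15, Otx2 and the deacetylase Sirt1 (-0.27 and -0.28). Chac1, Trib3 and Atf4 rose in both. Id3 fell in the GSK3α line (-0.20) and rose in the other (0.66), as did Nr5a2 (-0.18 and 0.38), whereas Fgf4 rose in the GSK3α line (0.14) and fell in the other (-0.52). In each of these 3 genes the response differed past the threshold between the lines. The GSK3α calls of Id3, Nr5a2 and Fgf4 each ended without any single library of that line, with adjusted p from 0.0658 to 0.374. That of Fgf4 was close to the threshold (adjusted p = 0.0497) and ended also with median-of-ratios scaling, limma-voom, either change of the filter, a pseudocount of 0.1 and the replicate block, and that of Nr5a2 with limma-voom. Both ended without inhibitor replicate 1 or 2 of the GSK3β line as well (0.0704 and 0.0711 for Fgf4, 0.0629 and 0.0632 for Nr5a2).

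**Figure D3:**
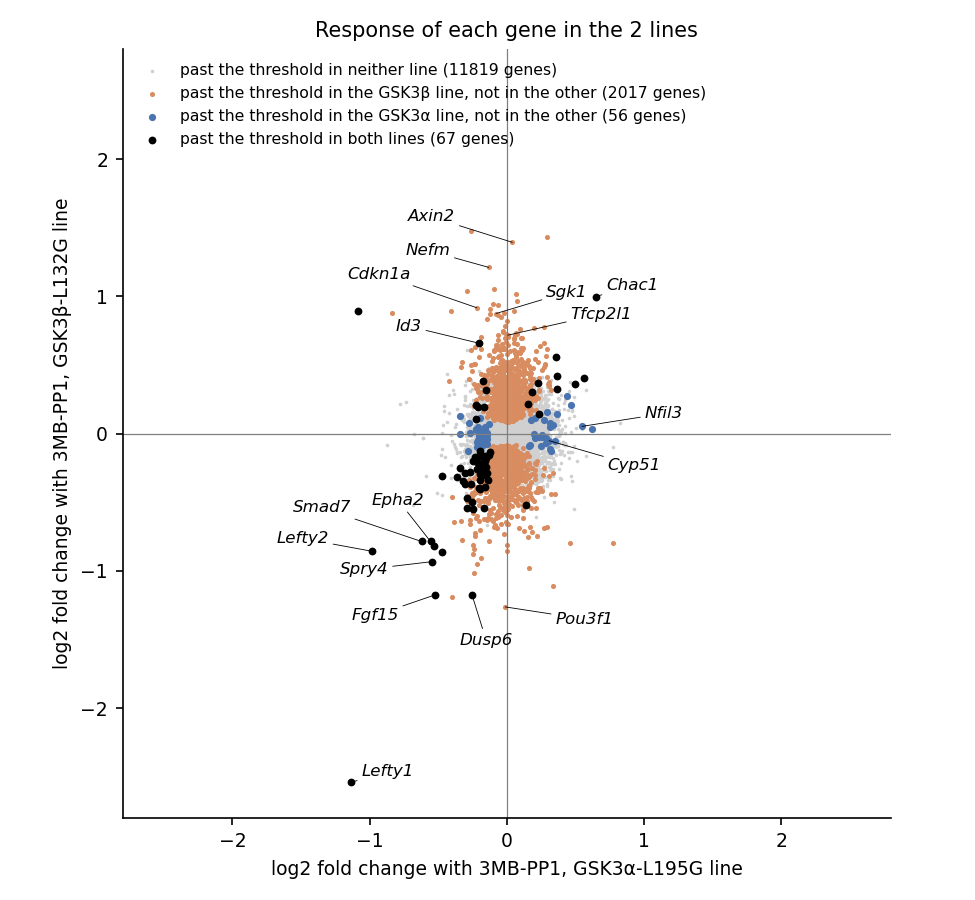
Response of each tested gene in both lines: log2 fold change with 3MB-PP1 in the GSK3α line (horizontal axis) and in the GSK3β line (vertical axis), coloured by which line passed the threshold. The 2017 genes past it in the GSK3β line and not in the other spread along the vertical axis, and Lefty1 lies farthest from the origin at -1.14 and -2.54.

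Averaged over both lines, with line as a term in the model, the inhibitor changed 241 genes, 92 higher and 149 lower, of which 14 changed at least 1.5-fold. Genes that responded in 1 line more than in the other have a wider spread in this model, which lowers their chance of a call. Nodal targets (7 of 14 lower; adjusted p = 7.69e-13, and adjusted p = 0.0969 with an estimated correlation), ERK feedback genes (6 of 14 lower; adjusted p = 7.52e-07, and adjusted p = 0.0718 with an estimated correlation) and formative genes (6 of 17 lower; adjusted p = 6.39e-12, and adjusted p = 0.142 with an estimated correlation) fell. ATF4 targets (9 of 24 higher; adjusted p = 3.82e-14, and adjusted p = 0.124 with an estimated correlation) and cholesterol and fatty acid genes (3 of 31 higher; adjusted p = 4.06e-07, and adjusted p = 0.115 with an estimated correlation) rose. The cholesterol and fatty acid list did not pass in the GSK3β line alone (camera adjusted p = 0.246). Its response was more negative there than in the GSK3α line. Adjusted over the list alone, 8 Nodal targets were lower, 8 ERK feedback genes lower and 1 higher, 10 formative genes lower, 16 ATF4 targets higher and 11 cholesterol and fatty acid genes higher. In all, 4 lists passed upward and 9 downward, and none passed with an estimated correlation. Among them were 2 lists of markers of other cell states. Primitive endoderm markers passed upward (adjusted p = 0.000746) with 0 of 10 members past the threshold and 5 higher adjusted over the list alone. In the GSK3α line alone that list did not pass (camera adjusted p = 0.314). The 2-cell-like markers passed downward (adjusted p = 0.0250) with 1 of 14 lower and 2 lower adjusted over the list alone. The count of genes was 102 with replicate number as a block. With single libraries left out it was 156 without inhibitor replicate 1 of the GSK3α line, and 106, 57, 74 and 52 without untreated replicates 1 and 2 and inhibitor replicates 1 and 2 of the GSK3β line.

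The untreated lines were compared to give the background between them, as the GSK3β line minus the GSK3α line. Of the 9 Y-linked genes tested 7 were higher in the GSK3β line and 1 was lower. The RNA helicase gene Ddx3y (chromosome Y, 1260771 to 1286629) had 5.14 ± 0.532 (SD, n = 2) in the GSK3α line and 108 ± 6.56 in the GSK3β line (log2 difference 4.15 ± 0.07, SE, adjusted p = 1.26e-18). Uty (4.22), Eif2s3y (3.50), Zfy1 (3.03) and Uba1y (2.44) were higher too, as were the X-linked Xlr5a (3.20), Xlr5c (3.20) and Xlr5b (2.82), close copies of each other. The imprinted RNA H19 (chromosome 7, 142575529 to 142578143) had 36.7 ± 0.486 in the GSK3α line and 4.87 ± 1.13 in the GSK3β line (log2 -2.70 ± 0.09, adjusted p = 1.13e-13). The nuclear RNA Neat1 (-1.58), the methyltransferase gene Bhmt (-2.05), Sfn (-1.67) and the mesoderm gene T (-1.36) were lower as well. Lefty1 (1.28), Lefty2 (1.04) and the Hedgehog receptor gene Ptch1 (1.23) were higher in the GSK3β line before any inhibitor was given, so the responses of the Lefty genes started from unlike levels. Lists started from unlike levels too. Formative, Nodal, G1/S, G2/M and cholesterol and fatty acid genes were higher in the untreated GSK3β line and responded more negatively there. Nucleolar MYC targets went the other way in both tests. The same untreated libraries enter the 2 tests with opposite sign.

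Between the untreated lines 6723 genes passed, 3111 higher and 3612 lower in the GSK3β line (3452 and 3342 with median-of-ratios scaling, which turns the balance), of which 904 differed at least 1.5-fold. SRF and YAP targets were higher in the GSK3β line (14 of 19; adjusted p = 5.85e-05), as were formative genes (10 of 17; adjusted p = 0.000313). ERK feedback genes were lower (12 of 14, such as Spry4 at -0.53 and Epha2 at -0.44; adjusted p = 5.11e-05). Each of the 3 lists had adjusted p = 0.132 with an estimated correlation. Adjusted over the list alone, 15, 11 and 14 members passed in these directions. G1/S genes (12 of 22 higher, 2 lower; adjusted p = 0.00367) and cholesterol and fatty acid genes (17 of 31 higher, 3 lower; adjusted p = 0.00466) were higher, again with adjusted p = 0.132 with an estimated correlation. With the adjustment over the list alone these were 13 and 2, and 17 and 3. Nucleolar MYC targets (2 of 24 higher, 13 lower; adjusted p = 0.00873), p53 targets (2 of 19 higher, 8 lower; 0.0253) and glycolysis and hypoxia genes (5 of 27 higher, 13 lower; 0.0253) were lower. Genes of G2/M (13 of 24 higher, 2 lower; 0.0164) and of the unfolded protein response (10 of 16 higher, 3 lower; 0.0298) and Nodal targets (7 of 14 higher, 2 lower; 0.0488) were higher. These 6 lists had adjusted p from 0.211 to 0.452 with an estimated correlation, and their counts adjusted over the list alone were equal but for 9 lower p53 targets and 14 higher G2/M genes. Of the 28 lists tested 11 passed, 7 upward and 4 downward, and none of them with an estimated correlation. Of the 135 named genes that passed, 103 passed whichever library was left out, among them every gene named for this comparison. By chromosome, the median log2 difference was 0.21 over 500 X-linked genes, -0.19 over 436 genes of chromosome 19 and 2.44 over 9 genes of the Y chromosome, and within 0.08 of 0 for every other chromosome. With 1 line per paralog, a difference between the clones and a difference between the paralogs are not separable in this comparison.

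**Figure D4:**
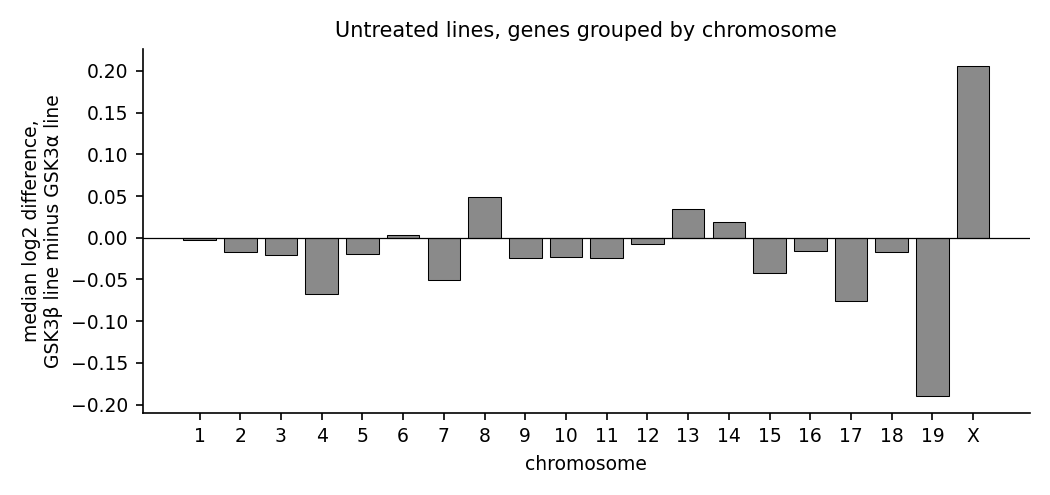
Median log2 difference between the untreated lines, GSK3β minus GSK3α, for the tested genes of each chromosome; each bar is the median over the genes of that chromosome. The bars of chromosome 19 (-0.19) and X (0.21) stand apart from the others, and the Y chromosome (2.44 over 9 genes) is not drawn.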

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

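The thinning of the reads and the test of an action of 3MB-PP1 on other kinases were chosen only after the result was seen. The results in this part stand here because a test of the difference itself, the change in the GSK3β line minus that in the GSK3α line, passed at an adjusted p of 0.05. This held for 911 genes and 15 gene lists and, among the named genes, for 89. With an estimated correlation 0 of the 15 lists passed.

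By the rule for named genes, with its minimum mean of 5, the 10 genes that responded most positively in the GSK3β line relative to the other were Axin2 (log2 difference 1.35), Nefm (1.34), Spic (1.15), Cdkn1a (1.14), Mobp (1.03), Pla2g7 (1.0), Sall3 (0.99), Platr13 (0.98), Sgk1 (0.95) and Tfap2c (0.89). Sp5, which lies under that minimum, had 1.14. All 10 rose in the GSK3β line and none passed in the GSK3α line. The 10 most negative by the same rule were Lefty1 (-1.40), Gadd45g (-1.26), Pou3f1 (-1.25), Rab43 (-1.04), Hspa1a (-0.97), Catip (-0.97), Dusp6 (-0.92), Cdkn1c (-0.91), Calca (-0.90) and Slc16a3 (-0.86). Of these, Lefty1 and Dusp6 fell in both lines, Rab43 passed in neither, and the others fell in the GSK3β line and did not pass in the GSK3α line. The call of Rab43 (adjusted p = 0.0325) ended without 5 single libraries: untreated replicate 2 (0.0988) and inhibitor replicates 1 and 2 (0.119 and 0.107) of the GSK3α line, and untreated replicate 2 (0.0518) and inhibitor replicate 2 (0.123) of the GSK3β line. The other 19 passed whichever library was left out.

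More genes passed with 3MB-PP1 in the GSK3β line (2084) than in the GSK3α line (123). Library depth was argued against, since with the estimated reads thinned to the smallest library the lowest ratio of these counts in 5 draws was 18.5. Replicate noise was argued against as well: the SD of the fold changes was 1.87 times that expected from the replicates in the GSK3β line and 1.15 times in the GSK3α line, a quotient of 1.62. The level of the mutant kinase stays open, because its RNA stood further above that of the same gene in the other line for GSK3β, by 1.08 on the log2 scale, and each paralog has 1 line. With that, unequal inhibition of the mutant kinases, a clone difference and a difference between the paralogs cannot be told apart.

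Of the Nodal targets and ERK feedback genes, 9 fell in both lines: Lefty1, Lefty2, Smad7, Skil, Dusp4, Dusp6, Epha2, Spry4 and Spry2, the last chosen after its values were seen. Leaving out single libraries left 6 of the 9 without either untreated library and 5 without either inhibitor library of the GSK3α line, 8, 8, 8 and 7 without untreated replicates 1 and 2 and inhibitor replicates 1 and 2 of the GSK3β line, and 8 with the replicate block. The choice of upper-quartile over median-of-ratios scaling was argued against as the cause, since all 9 stayed lower in both lines with the latter. The 2 scalings differ little here. With median-of-ratios scaling the median log2 change over all genes went from 0.0070 to 0.0011 in the GSK3α line. In the GSK3β line it went from -0.0057 to 0.00074. An error that both scalings share is therefore not covered. Library depth was argued against as well, with 8 of the 9 in the median of 5 thinned draws. An action of 3MB-PP1 on other kinases than the mutant GSK3 stays open because no line without a mutant kinase was measured, and it cannot be told apart from inhibition of GSK3 here. The response of 5 of the 9 differed between the lines (Lefty1, Dusp6, Epha2, Spry4 and Skil), each falling further in the GSK3β line, although the call of Skil ended without 5 single libraries (untreated replicate 2 and inhibitor replicates 1 and 2 of the GSK3α line, adjusted p = 0.104, 0.0585 and 0.116, and untreated replicate 1 and inhibitor replicate 1 of the GSK3β line, 0.0826 and 0.165).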

How the results depend on the processing

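The thinning of the estimated reads to the smallest library was chosen after seeing the data. Counts for the GSK3α line, the GSK3β line, the difference between the lines, the untreated lines and the average over both lines are given in this order, and were 123, 2084, 911, 6723 and 241 as reported. They were 141, 2148, 947, 6794 and 230 with median-of-ratios scaling, 97, 2264, 850, 6536 and 323 with limma-voom, 118, 1985, 810, 6950 and 226 without a filter, 121, 2070, 899, 6751 and 239 with the stricter filter, and 121, 2056, 904, 6704 and 234 with a pseudocount of 0.1. Of the genes that passed as reported, none changed direction under these scaling, voom, filter and pseudocount alternatives. Each line fitted alone gave 168 and 1941. With a fold threshold of 1.5 the counts fell to 6, 143, 136, 904 and 14, since that threshold removes small changes. Lists past the threshold were 10, 14, 15, 11 and 13 as reported, 3, 0, 0, 0 and 0 with an estimated correlation, where the test by its construction has the few residual degrees of freedom of the libraries in place of the number of genes, and 5, 16, 14, 22 and 8 with fry, where the cause was not tested.

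With the replicate number as a block the average over both lines fell to 102 genes, and the cause was not tested. The other counts were 106, 1997, 831 and 6648, and the lists 10, 14, 14, 10 and 13. Replicate differences of the groups correlated from -0.0447 to 0.0271 over genes, so libraries with the same replicate number showed no shared shift.

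Leaving out 1 library at a time, which leaves a lone library assumed to vary like the other groups, gave 16 to 186, 864 to 2277, 353 to 1339, 5669 to 6554 and 52 to 232 genes, and 7 to 12, 12 to 16, 11 to 17, 10 to 12 and 10 to 13 lists. Fewer libraries leave fewer degrees of freedom. Msmo1, which did not differ between the untreated lines (adjusted p = 0.981), passed at -0.11 (adjusted p = 0.0285) without untreated replicate 1 of the GSK3β line and at 0.11 (0.0313) without replicate 2, a difference with no direction here. Beyond these, of the named-gene results 13 lost and 3 gained a call with limma-voom, 7 and 6 with median-of-ratios scaling, 11 and 1 without a filter, 3 and 1 with a pseudocount of 0.1, and 9 and 2 with the block. The list of NRF2 targets lost its call for the difference with median-of-ratios scaling and with the block. The correlation of the lines ran from 0.0431 with limma-voom to 0.0995 with a pseudocount of 2. Thinning gave medians of 100, 1924, 789, 6360 and 222 genes, with 84 to 104 in the draws of the GSK3α line against 123 as reported. Thinning shows the counts at a smaller depth and not what a greater depth would add. In addition, 3529 genes with a mean value under 1 were not tested. The count-based tests and scalings of the design were not run because the deposited values are not counts.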

Other observations

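The tests of Y chromosome loss and of the number of X chromosomes, and the limit to splits with 2 libraries of each line, were chosen only after the result was seen. None of the 37 mitochondrially encoded genes listed had a value (0 of 37), but nuclear copies that collect such reads did. The genes named in this paragraph were chosen after their values were seen. In the GSK3β line Gm13340 (log2 0.66), Gm29216 (0.61), Gm28661 (0.57), Gm10925 (0.26) and Gm28437 (0.17) rose with inhibitor. Their summed values were 14015 and 14618 in the untreated GSK3α line and 13889 and 14075 with inhibitor, and 10367 and 10026 in the untreated GSK3β line and 13808 and 13663 with inhibitor. The ribosomal RNA gene Rn18s-rs5 ran from 817 to 4232 across the 8 libraries, with 4232 and 1362 in the untreated libraries of the GSK3α line.

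Between the untreated lines 7 of 9 Y-linked genes were higher in the GSK3β line and 1 lower, 257 of 500 X-linked genes were higher and 66 lower, and 56 of 436 genes of chromosome 19 were higher and 222 lower. Reads moved to the X-linked copies stay open. The median log2 difference of 7 such copies was -0.080, where a transfer was set to need a value under -0.3, and single copies ran from -0.18 to 0.31. That limit took no account of the median of 0.21 over all X-linked genes, so the test cannot decide. A different number of copies of the X chromosome in most cells stays open, with a median of 0.21 over the X-linked genes. Loss of the Y chromosome in most cells of the GSK3α line may be the cause but stays open. Of the 9 Y-linked genes 55.6% (5 of 9) were at least 4-fold lower there, under the 80% set for it. The share was 83.3% of the 6 genes without a Gm number, a subset chosen after the values were seen. The GSK3β line over the other was 43.2-fold for Zfy1 and 21-fold for Ddx3y. It was 3.86-fold for Kdm5d, at low means of 2.69 and 0.696. Gm37158 had 0.913-fold, at means of 298 and 327. Kdm5d and Gm37158 were chosen after their values were seen. A Y-linked gene without reads in any 1 library has no value here and could not count, so the share can understate a loss. Gain or loss of a whole autosome stays open at -0.19 for chromosome 19, since both medians lie in size between the limits for a cause (0.3) and against it (0.15), and no biological explanation was tested.

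The average effect of 3MB-PP1 over both lines was set against other splits of the 8 libraries into 4 and 4, with line as a term. In 1 of the 34 splits that could be fitted as many genes passed, the real one, with 241 genes by limma-trend, and the highest of the others was 0. A further split equals the division into lines and could not be fitted. Because the lines differ, only the 18 splits with 2 libraries of each line are comparable with the real one, too few for a share under 0.05. The other splits also put the response of the libraries into the spread, which lowers their counts.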
